A study of Danio rerio with 8 samples.

How the data were processed

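Zebrafish primordial germ cells (PGCs), the precursors of eggs and sperm, had been labelled by injected mRNA that codes for GFP and carries the nanos1 3′ UTR. Fluorescent cells were picked by hand from dissociated embryos, and cells of one genotype were pooled once the remaining somatic cells had been typed. The pools came from wild type embryos and from embryos homozygous for a mutation of pigu, at the shield stage (early gastrula) and the bud stage (end of gastrulation). Each of the 4 groups had 2 libraries, described in the labels as biological replicates and made by SMART-seq2. The labels do not describe the pigu allele, one protocol field speaks of oocytes, and nothing states whether the replicate numbers pair samples across groups.

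The deposited table holds FPKM (fragments scaled to transcript length and to the mapped fragments of the library), 1 column per library. Processing notes of the authors list Trim Galore, STAR 2.5.3a, Cufflinks 2.2.1 and the genome build danRer11. The annotation and the handling of reads with several alignments are not stated. Sequencing depth is unknown, since FPKM carry no read counts, so no counting interval is given. The table holds 31934 entries for 31200 symbols and no coordinates, and genes are named here by the symbol alone. For the 545 symbols with several entries the entry with the highest mean FPKM was kept, and 2 entries with a missing value were left out.

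Values were taken as log2(FPKM + 1) with no further scaling. Genes with FPKM of at least 1 in at least 2 of the 8 libraries were tested, 13984 in all. One limma-trend fit (limma 3.58.1 in R 4.3.3) of the 4 group means gave 6 comparisons, which are the genotype at shield, at bud and over both stages, the stage in each genotype, and the interaction of genotype and stage. The fit has 4 residual degrees of freedom and 15.4 after moderation. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

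The 32 gene lists cover GPI anchor synthesis and attachment, secretion, stress, germ cell and somatic cell types, signalling targets, ribosomal and mitochondrial genes and histones. Each had at least 5 tested members and was tested with camera, which asks whether a list ranks above or below the other genes, at a preset correlation of 0.01 between genes. Adjustment was over the 32 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone.

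Genes named in the text follow a rule. For genotype it takes the 10 largest changes each way among called genes whose libraries do not overlap and whose higher group has a mean FPKM of at least 5. Where fewer than 5 pass, it takes the 5 with the smallest unadjusted p each way under the same filters on overlap and mean FPKM. These are named as not having passed. Their lack of overlap is set by the rule and is no result. The stage comparisons and the interaction use 5 each way. The rule adds the transamidase subunits and up to 4 members per list with the smallest p, and leaves out unnamed loci. Any other gene named was chosen after its values were seen.

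The comparisons, filter, tests, lists and rule and all but 2 of the alternatives were fixed before the data were examined. Tests of the lists in the stage comparisons were added later and were not repeated under the alternatives. The alternatives changed the pseudocount (0.1 or 5), the filter, the scaling (median of ratios, quantile), the moderation, the library weights, the threshold, a replicate block, the merging of entries and the libraries included.

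The fit was tested on simulated data for the shield comparison, with 200 of 13984 genes changed in each of 10 runs. The changed genes were drawn only from those with a higher mean level, so recovery of genes with low FPKM was not simulated. With an SD of 0.3 it recovered 100% of the changed genes. With the spread of these libraries it recovered 2.4% of all genes changed 4-fold up or down, 24.5% of those changed 16-fold and 55.2% of those changed 64-fold, with 3.7 false calls per run. Among the raised genes alone the shares were 4%, 37.8% and 85.7%, so that lowered genes were recovered less often. Camera called a list of 20 genes raised by 2 log2 units in 10 of 10 runs, and 1 other list. The noise was drawn for each gene on its own. These runs therefore cannot show how often camera calls a list whose genes vary together.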

Results

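The series compares gene expression of PGCs from wild type and pigu mutant embryos. pigu codes for a subunit of GPI transamidase, the enzyme that attaches glycosylphosphatidylinositol (GPI) anchors to proteins in the endoplasmic reticulum, and the series asks how this complex affects PGC migration. Each of the 4 groups had 2 pooled libraries. Total FPKM for replicates 1 and 2 were 857851 and 605811 in wild type shield, 769946 and 643244 in mutant shield, 709383 and 606573 in wild type bud, and 764458 and 720337 in mutant bud. Read depth is unknown.

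The libraries differed in how many genes they detected. Genes with FPKM of at least 1 numbered 8338 and 12293 in the wild type shield libraries, 5878 and 12046 in mutant shield, 11460 and 13007 in wild type bud, and 6708 and 12037 in mutant bud. Entries of the mitochondrial genome took 58.3% and 22.9% of the total FPKM in wild type shield, 72.2% and 23.5% in mutant shield, 30.5% and 17.8% in wild type bud, and 37.3% and 17.3% in mutant bud. Across the tested genes, Pearson's r of log2 values between the replicates was 0.80 in wild type shield, 0.68 in mutant shield, 0.90 in wild type bud and 0.64 in mutant bud. The median log2 difference of all genes between mutant and wild type was −0.30 at shield and −0.51 at bud. After median-of-ratios scaling it was −0.16 and −0.33, and after quantile normalization 0.05 and 0.04. Medians of gene lists are therefore given relative to the median of all genes. Counts of members higher or lower use the difference itself, with this median not taken off. At shield and at bud such counts therefore lean to the lower side.

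**Figure D1:**
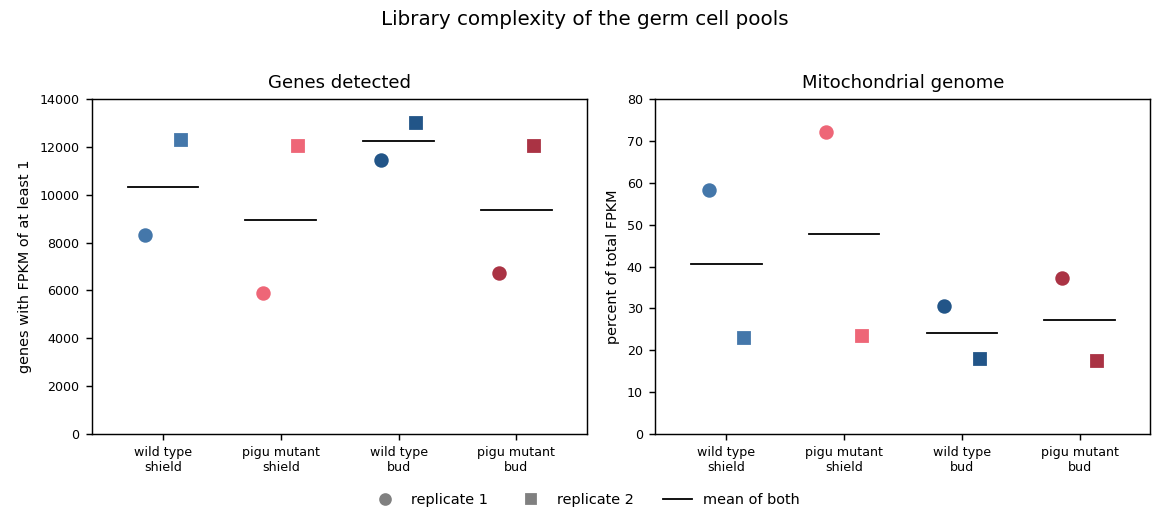
Genes with FPKM of at least 1 (left) and percent of total FPKM in entries of the mitochondrial genome (right) in each library, with the mean of both as a line. Replicate 1 detected fewer genes than replicate 2 in each group, with 5878 in mutant shield as the lowest value.

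The mutated gene itself was read in 7 of the 8 libraries. The FPKM of pigu were 11.5 and 15.0 in wild type shield, 0.81 and 10.95 in mutant shield, 2.78 and 14.6 in wild type bud, and 0 and 7.32 in mutant bud. Its log2 difference between mutant and wild type was −1.60 (SE 1.70, limma adjusted p = 1) at shield and −1.41 (SE 1.70, adjusted p = 0.961) at bud, and neither passed the test. Without mutant shield replicate 1 the shield value was −0.24, and without mutant bud replicate 1 the bud value was 0.12. pigk, the catalytic subunit, stood at 5.10 and 4.02 in wild type shield and 4.48 and 8.83 in wild type bud, against 0 and 0.19 in mutant shield and 0 and 0.18 in mutant bud. Its log2 difference over both stages was −2.55 (SE 0.85, limma adjusted p = 0.983). This made pigk the 1 subunit of 5 that passed when adjusted over the list alone (adjusted p = 0.043), and 0 of 5 passed over all genes tested. The other subunits varied with the library. gpaa1 was listed at 0 in mutant shield replicate 1 and mutant bud replicate 1 but stood higher in mutant bud replicate 2 than in both wild type bud libraries (2.06 and 5.88). pigs was listed at 0 in mutant bud replicate 1 and at 24.4 in replicate 2, and pigt at 0 and 3.43. The list as a whole was not called over both stages (camera adjusted p = 0.092), at shield (0.18) or at bud (0.32).

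**Figure D2:**
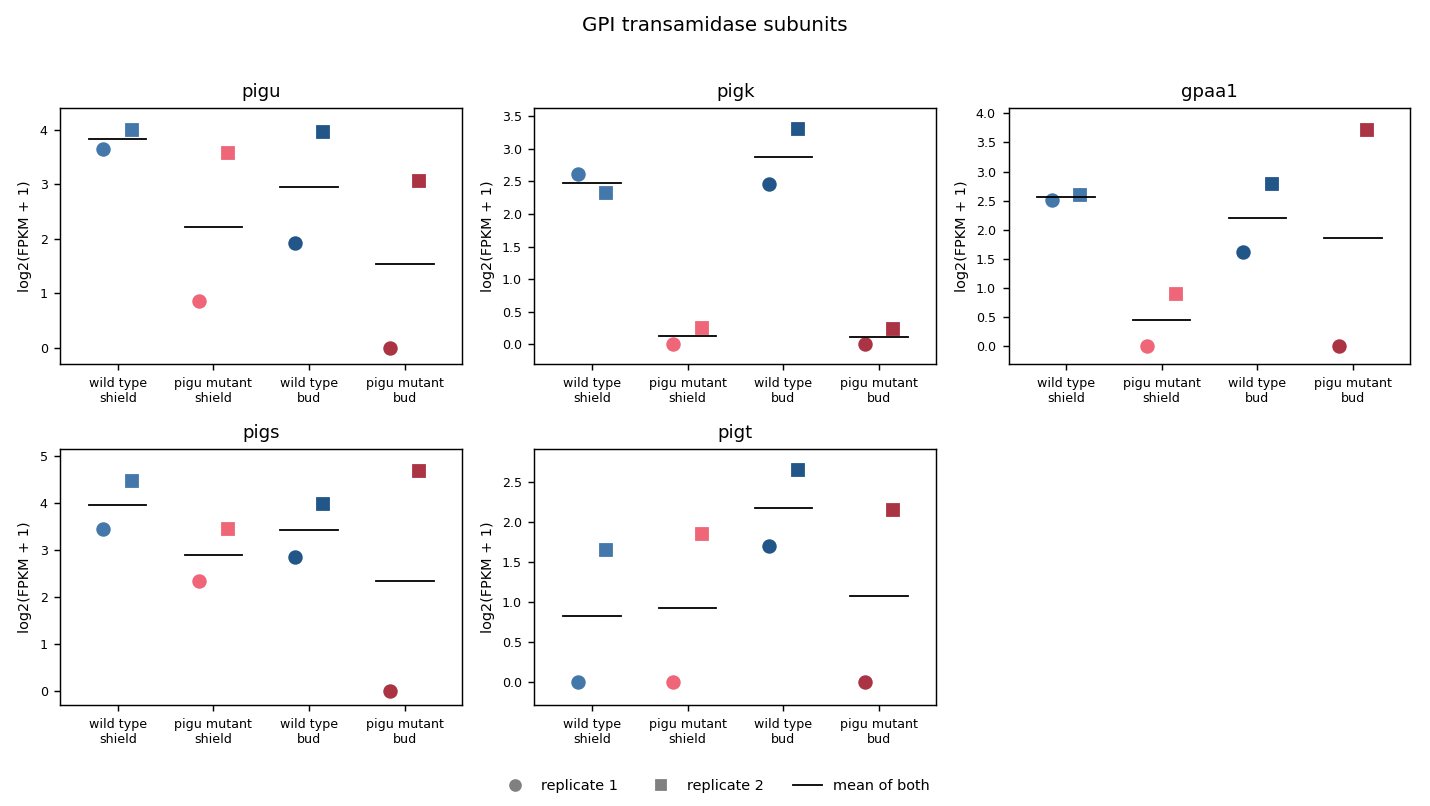
log2(FPKM + 1) of the 5 GPI transamidase subunits in each library, with the mean of both as a line. pigk FPKM are at most 0.19 in the 4 mutant libraries and at least 4.02 in the 4 wild type libraries.

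Over both stages, the comparison that uses all 8 libraries for genotype, no gene passed the test. The genes named here lay apart in every mutant library at the same stage, which the rule asks for. atp5if1a, which codes for the inhibitor of the mitochondrial ATP synthase, stood at 30.1 and 29.9 FPKM in wild type shield against 221 and 286 in mutant shield, and at 90.2 and 77.2 in wild type bud against 436 and 524 in mutant bud. Its log2 difference was 2.77 (SE 0.55, limma adjusted p = 0.957), and it passed when adjusted over the list alone among 76 tested genes of oxidative phosphorylation (adjusted p = 0.01). Cytoplasmic actin, actb1, stood at 72.2 and 103 in wild type shield against 206 and 300.0 in mutant shield, and at 323 and 265 against 1180 and 1091 at bud (log2 difference 1.73, SE 0.49). sec11a, a subunit of the signal peptidase, had FPKM of 0 and 0.21 in wild type shield against 44.2 and 33.4, and 2.43 and 5.10 in wild type bud against 29.2 and 11.5. nlrc3 was listed at 0 in the 4 wild type libraries and had 26.3 and 30.7 in mutant shield and 18.04 and 2.21 in mutant bud. anapc11, of the anaphase-promoting complex, stood at 176 and 67.3 in mutant shield against 0 and 29.1, and at 124 and 74.7 in mutant bud against 51.4 and 0.

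Lower in the mutant libraries of both stages were the importin kpna7, the translation repressor eif4ebp1, the Golgi protein gene yipf5, gnpda1 and thy1. kpna7 stood at 239 and 228 in wild type shield against 27.5 and 102, and at 122 and 112 in wild type bud against 23.4 and 6.44 (log2 difference −2.62, SE 0.70). eif4ebp1 stood at 28.4 and 47.2 against 7.46 and 10.6 at shield, and at 37.1 and 67.9 against 0.58 and 1.38 at bud (−3.33, SE 0.90). yipf5 stood at 105 and 154 against 17.3 and 85.4 at shield, and at 114 and 118 against 0 and 5.79 at bud (−3.59, SE 0.85). gnpda1 had a log2 difference of −3.53 (SE 0.96). thy1, whose product carries a GPI anchor, stood at 151 and 94.4 against 1.66 and 80.8 at shield, and at 26.6 and 29.2 in wild type bud while listed at 0 in both mutant bud libraries. Each of these 5 genes had a limma adjusted p of 0.983. The smallest adjusted p was that of the unnamed locus BX571711.1, which lies outside the rule and was chosen after its values were seen (0.0736). Its FPKM were 2187 and 111 in wild type shield and 37.5 and 52.1 in wild type bud, and it was listed at 0 in the 4 mutant libraries.

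limma called 0 genes over both stages, and 597 had an unadjusted p under 0.05 where 699.2 would be found by chance. That count depends on how the spread between replicates is modelled, as given below with the processing. Fully separated in both stages were 59 genes higher and 623 lower in the mutant, or 0.4% and 4.5% of genes. The chance for a single gene is 2.8% each way, but genes shift together with a library. With a filter at FPKM of 5 the locus BX571711.1 was called, and leaving out wild type bud replicate 1 or 2 gave 3 and 2 calls.

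**Figure D3:**
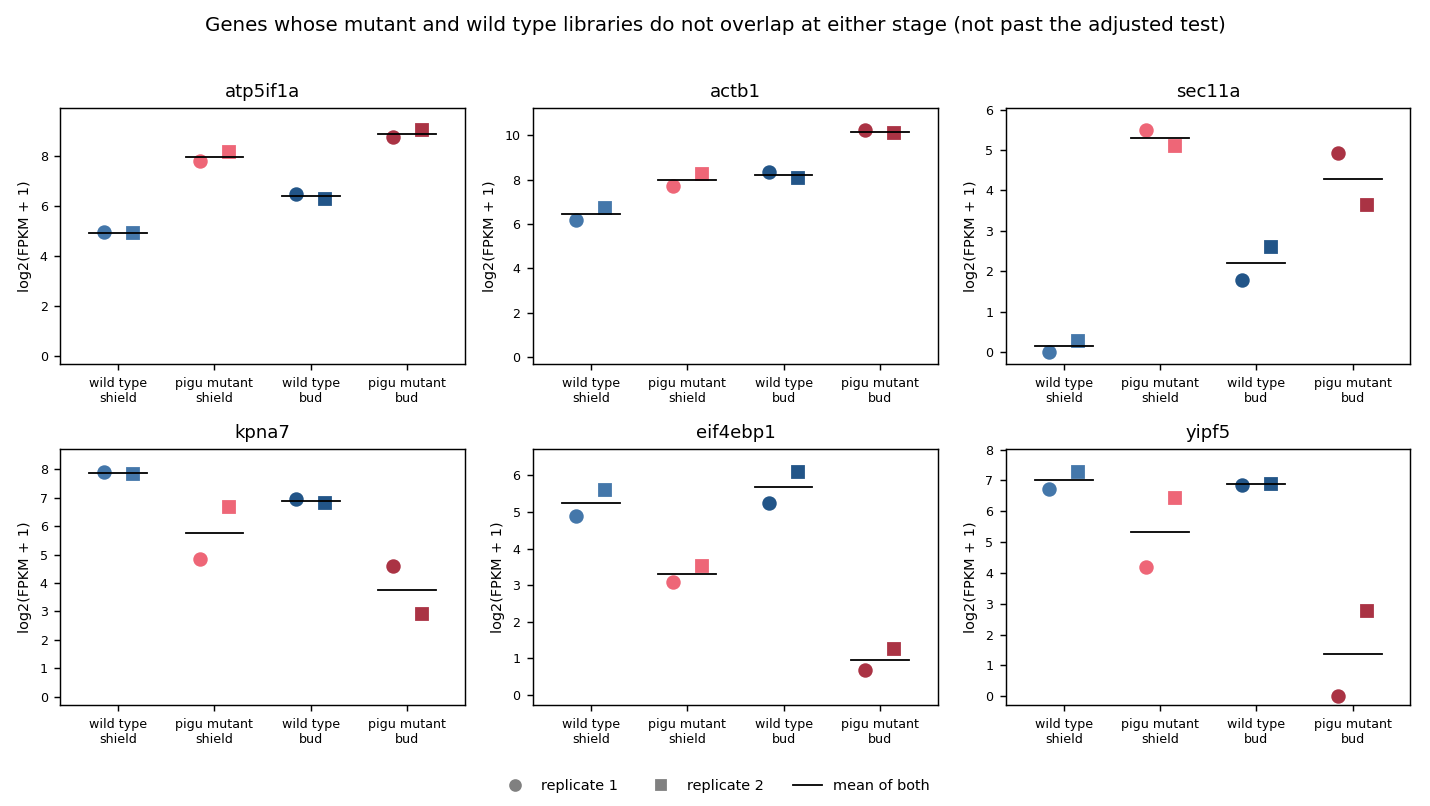
log2(FPKM + 1) of 6 genes in each library, with the mean of both as a line. The mutant libraries of each stage lie all above (atp5if1a, actb1, sec11a) or all below (kpna7, eif4ebp1, yipf5) the wild type libraries of that stage, and none of the 6 passed the adjusted test. The rule by which genes are named asks for this separation.

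Over both stages camera called 12 of the 32 lists, all as higher in the mutant. With an estimated correlation none of the 12 was called (smallest adjusted p = 0.84), nor with fry (0.85). The mitochondrially encoded protein genes lay at 1.12 relative to all genes (13 of 13 members higher, adjusted p = 1.4e-09), neural ectoderm at 1.43 (18 of 20, 2.5e-10), enveloping layer at 1.35 (11 of 13, 1.1e-05), axial mesoderm at 0.92 (0.0033), retinoic acid targets at 0.98 (0.0058), histones at 0.67 (0.013), paraxial and lateral mesoderm at 0.62 (0.0023), FGF targets at 0.60 (0.027) and ribosomal protein genes at 0.48 (45 of 80, 1.8e-05). Adhesion and matrix genes lay at 0.33 (0.027), mesendoderm at 0.32 (0.027) and Nodal targets at 0.28 (0.046). Before the median of all genes, −0.42, was taken off, the medians of these 3 lists were below 0, at −0.08, −0.10 and −0.14, and their means were −0.05, 0.11 and 0.16. After quantile normalization the value of the mitochondrial genes was 0.72 and that of the ribosomal protein genes 0.07, and the calls of the ribosomal, histone, FGF, mesendoderm and Nodal lists were lost. Median-of-ratios scaling also ended the mesendoderm and Nodal calls. The adhesion and Nodal calls ended with a pseudocount of 0.1, with no filter and with the filter at FPKM of 5, the retinoic acid call with that filter, and the paraxial and lateral mesoderm call with no filter. With FPKM of at least 1 in all libraries the adhesion, mesendoderm and FGF calls were lost. The adhesion call was kept in 11 of 23 alternatives, the mesendoderm call in 13 of 23 and the Nodal call in 9 of 22. Without mutant bud replicate 2 only 2 lists were called, and 6 without mutant shield replicate 1 and 7 without wild type bud replicate 2. The mitochondrial call ended without wild type shield replicate 2 (adjusted p = 0.14). Without both mutant shield replicate 1 and mutant bud replicate 2 the direction turned to lower for the enveloping layer (adjusted p = 0.8) and the ribosomal protein genes (0.4). Except for oxidative phosphorylation and the transamidase, each with 1 member, no list had a member that passed when adjusted over the list alone, and 0 passed over all genes.

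At shield, during early gastrulation, gene groups of the secretory route were called lower in mutant PGCs. Endoplasmic reticulum chaperones lay at −0.61 relative to all genes, with 28 of 31 members lower (camera adjusted p = 0.02). Secretory transport genes lay at −0.52, with 39 of 43 lower (adjusted p = 0.02). Other lists lay lower still without a call, among them axial mesoderm (−1.03), Nodal targets (−0.82), mesendoderm (−0.81) and GPI synthesis (−0.76). A low value was thus not particular to the secretory route. Histone genes were called higher, at 0.54, with 12 of 17 members higher (adjusted p = 0.02). With an estimated correlation the 3 calls had an adjusted p of 0.99. Examples, none past the test, were the translocon gene sec61b with 651 and 479 FPKM in wild type against 214 and 286 in mutant, the chaperone hsp90b1 with 52.6 and 86.2 against 17.1 and 35.8, the coat protein gene copg2 with 42.3 and 88.0 against 0 and 39.4, and hist1h2a11 with 1.04 and 13.04 against 66.6 and 20.02. The secretory transport call ended without mutant shield replicate 1 or wild type shield replicate 2 (adjusted p up to 0.63), as did the histone call (up to 0.97). The chaperone call ended without either replicate 2 at shield (up to 0.13). After median-of-ratios scaling the chaperone and secretory transport calls were lost, and the histone list stayed called. The secretory transport call was also lost with only the libraries compared and with FPKM of at least 1 in all libraries. The directions of the 3 lists held under both scalings, but that of the histones turned to lower without mutant shield replicate 1 and mutant bud replicate 2 (adjusted p = 0.81).

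Among single genes at shield, limma called 0, and 201 had an unadjusted p under 0.05. Leaving out wild type bud replicate 1 or 2, which enter through the shared spread, gave 1 and 2 calls. Among genes that pass the filters of the rule, atp5if1a had the smallest p on the higher side (log2 difference 3.03, SE 0.78, limma adjusted p = 1). Next came sec11a (5.16, SE 1.46), nlrc3 and the solute carrier slc45a3 with 10.6 and 3.61 FPKM against 0 and 0.35. GPHB5 followed with 6.59 and 19.9, listed at 0 in wild type shield. On the lower side stood fbxw11b with 21.9 and 75.9 FPKM in wild type against 0.39 and 0 in mutant, the complex I subunit ndufs6 with 71.1 and 34.6 against 0 and 7.85, GNG12 with 32.7 and 20.8 against 0 and 1.69, il13ra2 with 10.5 and 5.84, and kcnn1b with 33.1 and 15.5. The last pair was listed at 0 in both mutant libraries. Of the 13984 genes, 596 were separated as higher and 1702 as lower. The chance for a single gene is 16.7% each way, but genes shift together with a library.

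Germ plasm genes, which mark PGCs, were not called at shield (6 of 19 members higher, adjusted p = 0.96). ddx4 stood at 319 and 889 FPKM in wild type and at 106 and 1264 in mutant, and dnd1 at 1485 and 4585 against 904 and 3798. GPI-anchored protein genes (12 of 32 higher and 18 lower, adjusted p = 0.62) and GPI synthesis genes (18 of 23 lower, adjusted p = 0.17) were not called either. The lists of GPI-anchored, germ plasm, adhesion, p53, dissociation stress and FGF genes had medians and means below 0, with the median of all genes not taken off, but a camera direction above the other genes, and were not called. Over the list alone, 0 members of the 32 lists passed at shield. Keratins of the enveloping layer, the outer epithelium of the embryo, were high in mutant shield replicate 1, with krt18a.1 at 265 and krt5 at 81.1, against 1.81 and 0.22 in replicate 2. The list was not called at shield (adjusted p = 0.069).

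At bud, 5 of the 7 lists of somatic cell type markers were called higher in mutant PGCs, with the highest values in replicate 2. Relative to all genes, axial mesoderm lay at 3.03 (11 of 11 members higher, camera adjusted p = 1.8e-08), neural ectoderm at 2.51 (20 of 20, 7.3e-15), enveloping layer at 1.73 (13 of 13, 2.8e-05), paraxial and lateral mesoderm at 1.68 (14 of 17, 7.9e-06) and mesendoderm at 1.50 (14 of 18, 2.4e-05). With an estimated correlation their adjusted p was 0.55 for neural ectoderm and 0.59 for the others. These lists share members, since 13 of 18 mesendoderm and 6 of 11 axial mesoderm genes are also in another list. Epidermis was not called, with 12 of 16 members lower (−0.57 relative to all genes, adjusted p = 0.40), nor were yolk syncytial genes (5 of 8 higher, 0.16). In mutant bud replicate 2 the notochord gene noto stood at 109 FPKM, the midbrain and pronephros regulator pax2a at 217, tbx6 of the paraxial mesoderm at 105, krt5 at 239 and the hatching gland gene ctslb at 264. In replicate 1 noto, pax2a and tbx6 were listed at 0, krt5 stood at 0.32 and ctslb at 11.2. six3b of the forebrain (73.5 and 54.5, listed at 0 in wild type bud), neurog1 (30.3 and 35.2, listed at 0 in wild type bud) and the segmentation clock gene her7 (253 and 94.2 against 2.89 and 11.3) were high in both mutant libraries. six3b and her7 passed when adjusted over the list alone (adjusted p = 0.021 and 0.047). At shield her7 already stood at 24.4 and 88.05 FPKM in wild type and at 22.0 and 271 in mutant.

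In the same replicate 2, germ plasm genes were low. ddx4 stood at 204 FPKM there, against 556 and 629 in wild type bud and 1401 in mutant bud replicate 1, and cxcr4b, the receptor that guides PGC migration, at 45.1 against 311 and 546 in wild type bud and 391 in mutant bud replicate 1. As a list, germ plasm genes were not called at bud (16 of 19 lower, adjusted p = 0.15), nor were PGC migration genes (27 of 34 lower, 0.40) or GPI-anchored protein genes (18 of 32 lower, 0.41).

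Of the signalling target lists, Nodal, retinoic acid and FGF targets were called higher at bud, while Wnt targets (8 of 16 higher, adjusted p = 0.16) and BMP targets were not called, the latter with 14 of 19 members lower (−1.02 relative to all genes, adjusted p = 0.33). Nodal targets lay at 1.95 (12 of 14 higher, adjusted p = 1.3e-06, 0.55 with an estimated correlation), retinoic acid targets at 1.97 (7 of 8, 0.00043, then 0.59), FGF targets at 1.03 (9 of 14, 0.0058, then 0.85) and adhesion genes at 0.89 (26 of 44, 0.0041, then 0.85). dkk1b, a Wnt antagonist and Nodal target, stood at 153 and 52.8 FPKM in mutant against 9.55 and 5.13 in wild type. Ribosomal protein genes lay at 0.89 (62 of 80 higher, 1e-09, 0.85 with an estimated correlation). This value was 0.88 after median-of-ratios scaling and 0.09 after quantile normalization, where the call was lost. The mitochondrially encoded genes lay at 2.17 (13 of 13 higher, 1e-17, 0.55 with an estimated correlation), with mt-atp8 at 31907 and 23835 FPKM against 10966 and 6968. After quantile normalization the list lay at 1.25. Without mutant bud replicate 2 only the mitochondrial list stayed called of the 12, and leaving out 1 library gave the others an adjusted p of up to 0.52. FGF and retinoic acid targets also lost their call without wild type bud replicate 2, and FGF targets, adhesion genes and mesendoderm with FPKM of at least 1 in all libraries.

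The p53 and apoptosis list was the one called lower in mutant bud PGCs (19 of 20 members, −0.90 relative to all genes, adjusted p = 0.013, 0.85 with an estimated correlation). It was highest in wild type bud replicate 2, where phlda3 stood at 93.6 FPKM, cdkn1a at 25.1, mdm2 at 57.2 and the interferon-induced isg15 at 91.9. In wild type bud replicate 1 these stood at 2.06, 1.77, 14.4 and 4.50, and isg15 was listed at 0 in mutant bud. The call ended without wild type bud replicate 2 or either mutant bud library (adjusted p up to 0.34). It also ended with the filter at FPKM of 5, with only the libraries compared and with FPKM of at least 1 in all libraries, and was kept in 15 of 24 alternatives.

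**Figure D4:**
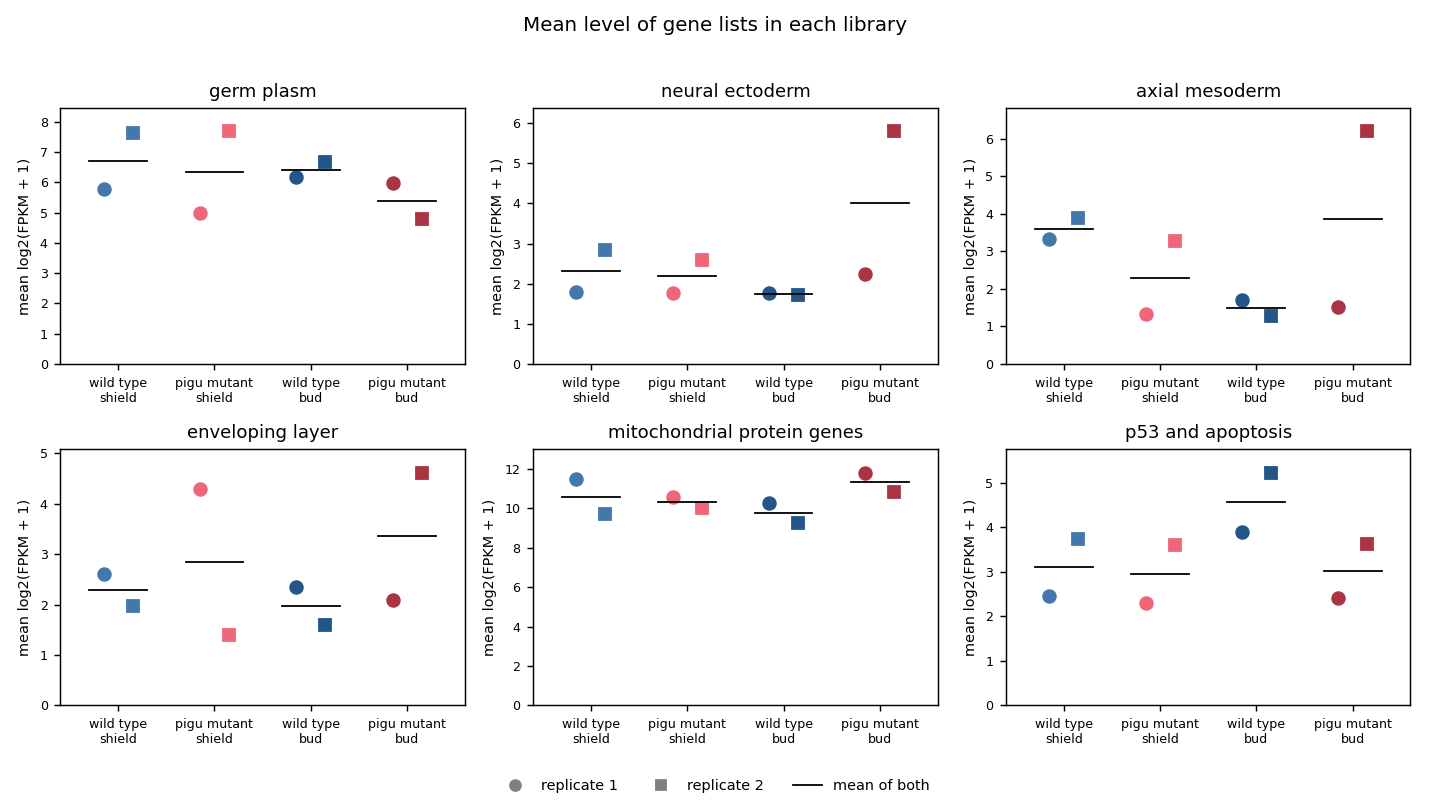
Mean log2(FPKM + 1) of 6 gene lists in each library, with the mean of both as a line. In mutant bud, neural ectoderm is at 5.80 in replicate 2 and 2.23 in replicate 1, and germ plasm at 4.79 and 5.97, while the mitochondrial protein genes are at 11.81 in replicate 1 and 10.83 in replicate 2.

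For single genes at bud limma called 0 as well, and 677 had an unadjusted p under 0.05. Without mutant bud replicate 2 the count stayed at 0, and without both this library and mutant shield replicate 1 it was 237, of which 10 were higher and 227 lower. That count rests on mutant bud replicate 1, which detected 6708 genes. Among genes that pass the filters of the rule, six3b had the smallest p on the higher side (log2 difference 6.01, SE 1.50, limma adjusted p = 0.959). Next came the transcription regulator prdm14 (19.1 and 7.74 FPKM in mutant, listed at 0 in wild type bud). The guidance factor ntn1a (20.8 and 13.8 against 0.18 in both), her7 and rnd2 (33.4 and 3.27, listed at 0 in wild type) followed. Lower ones were yipf5 (−5.49, SE 1.2), dennd2da (9.68 and 11.8 in wild type against 0 and 0.24), plekho1a (4.86 and 8.05, listed at 0 in mutant), eif4ebp1 (−4.72, SE 1.27) and tmem170a (4.60 and 5.55, listed at 0 in mutant). Separated genes numbered 1145 higher (8.2%) and 4043 lower (28.9%). The chance for a single gene is 16.7% each way, but genes shift together with a library, so these shares have no fixed chance level. For bud against shield in wild type, 29.1% were separated as higher and 9.9% as lower. The lists of GPI-anchored protein, chaperone, ATF4, secretory, Wnt, cell cycle and oxidative phosphorylation genes had medians below 0, with the median of all genes not taken off, but a camera direction above the other genes, and none was called. Among members adjusted over the list alone, six3b and her7 were the only ones of the 32 lists.

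In wild type PGCs, camera called the maternal transcripts lower and the ribosomal protein genes higher at bud than at shield, and neither call held with an estimated correlation (adjusted p = 0.42 and 0.99). The maternal and oocyte list lay at −1.39 relative to all genes, whose median was 0.51 (0.20 after median-of-ratios scaling and 0.01 after quantile normalization), with 25 of 26 members lower (camera adjusted p = 7.8e-14). ccna1, the germline cyclin A, stood at 549 and 609 FPKM at shield and at 22.6 in both bud libraries (log2 difference −4.62, SE 1.05). tdgf1, the Nodal co-receptor, stood at 128 and 227 against 5.16 and 13.7, btg4 of maternal mRNA clearance at 48.3 and 41.4 against 2.27 and 1.23, and nanog at 89.5 and 427 against 22.9 and 38.6. In this list 2 members passed when adjusted over the list alone (smallest adjusted p = 0.012), and 0 passed over all genes. Nodal targets (13 of 14 lower, adjusted p = 3.1e-09, 0.42 with an estimated correlation), axial mesoderm (9 of 11, 5e-08, then 0.69) and mesendoderm (17 of 18, 6.8e-08, then 0.69) were called lower, as were neural ectoderm (0.0011), enveloping layer (0.036), germ plasm (0.035) and the mitochondrially encoded genes (13 of 13, 8.2e-09, then 0.85). The first 3 of that last group had an adjusted p of 0.99 with an estimated correlation. Germ plasm had 11 of 19 members lower and 8 higher, with a median of −0.06 before the median of all genes was taken off. The mitochondrial genes had a mean log2 level of 11.48 and 9.70 at shield and 10.28 and 9.25 at bud, so the stages overlapped.

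Ribosomal protein genes were called higher in wild type bud (75 of 80 members, adjusted p = 1.2e-08), with rpl7 at 212 and 134 FPKM at shield and 647 and 474 at bud. Oxidative phosphorylation genes (65 of 76, 0.026) and p53 genes (17 of 20, 0.0073) were called higher too, and each of these 3 had an adjusted p of 0.99 with an estimated correlation. limma called 0 genes, with 467 at an unadjusted p under 0.05. The named genes with the smallest p were dennd2da, plekho1a, tmem170a, isg15 and pimr68, listed at 0 in wild type shield, and on the lower side ccna1, GNG12, il13ra2, the claudin cldnd (230 and 199 against 10.9 and 7.91) and the BMP target id1 (2243 and 2320 against 366 and 248). Among other lists, 1 member passed over the list alone for Nodal targets (smallest adjusted p = 0.037) and 1 for BMP targets (0.041).

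In mutant PGCs the same 2 themes were called at bud. The maternal list lay at −1.90 relative to all genes, whose median was 0.25 (20 of 26 lower, adjusted p = 4.1e-07, 0.95 with an estimated correlation) and the ribosomal protein genes at 1.40 (78 of 80 higher, 3.4e-21, then 0.95). The ribosomal value was 0.80 after quantile normalization. ccna1 stood at 188 and 371 FPKM in mutant shield and at 0 and 5.09 in mutant bud (log2 difference −6.75, SE 1.05, limma adjusted p = 0.125), cldng at 294 and 268 against 0 and 8.16 (−6.54, SE 1.07, adjusted p = 0.125), inka1a at 107 and 361 against 1.28 and 4.34, and cth1 at 117 and 212 against 6.65 and 4.81. lsm14b stood at 41.5 and 151 and was listed at 0 in mutant bud. On the higher side were fbxw11b (0.39 and 0 against 74.3 and 26.8), ndufs6 (0 and 7.85 against 96.2 and 90.1), elavl1b (0 and 23.3 against 241 and 174), dkk1b (2.65 and 0.34 against 153 and 52.8) and eef2a.1 (listed at 0 in shield, 80.9 and 45.3 at bud). limma called 0 genes, with 928 at an unadjusted p under 0.05. After median-of-ratios scaling 7 were called, all lower at bud, among them ccna1, cldng, inka1a, lsm14b and cth1, while leaving out wild type bud replicate 1 or 2 gave 9 and 7. Without mutant shield replicate 2 there were 195, of which 187 were higher and 8 lower at bud. That count rests on mutant shield replicate 1, which detected 5878 genes.

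Camera called 12 lists for stage in mutant PGCs. Besides those above these were retinoic acid targets (8 of 8 higher, 0.00031), oxidative phosphorylation (62 of 76, 0.00056), the mitochondrially encoded genes (13 of 13, 0.0019), neural ectoderm (0.0031), paraxial and lateral mesoderm (0.022), secretory transport, adhesion, yolk syncytial and Wnt target genes (0.043 each) as higher, and germ plasm genes as lower (13 of 19, 0.0031). Each had an adjusted p of 0.95 with an estimated correlation. Neural markers and germ plasm genes here carry the values of mutant bud replicate 2 given above. Mean log2 levels in mutant bud replicates 1 and 2 were 2.45 and 5.81 for retinoic acid targets and 1.56 and 4.83 for paraxial and lateral mesoderm. They were 2.39 and 5.07 for Wnt targets and 2.64 and 4.05 for adhesion genes. The mitochondrial genes were higher in replicate 1 (11.81 and 10.83). The largest number of members adjusted over the list alone was 2, in oxidative phosphorylation (smallest adjusted p = 0.048).

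**Figure D5:**
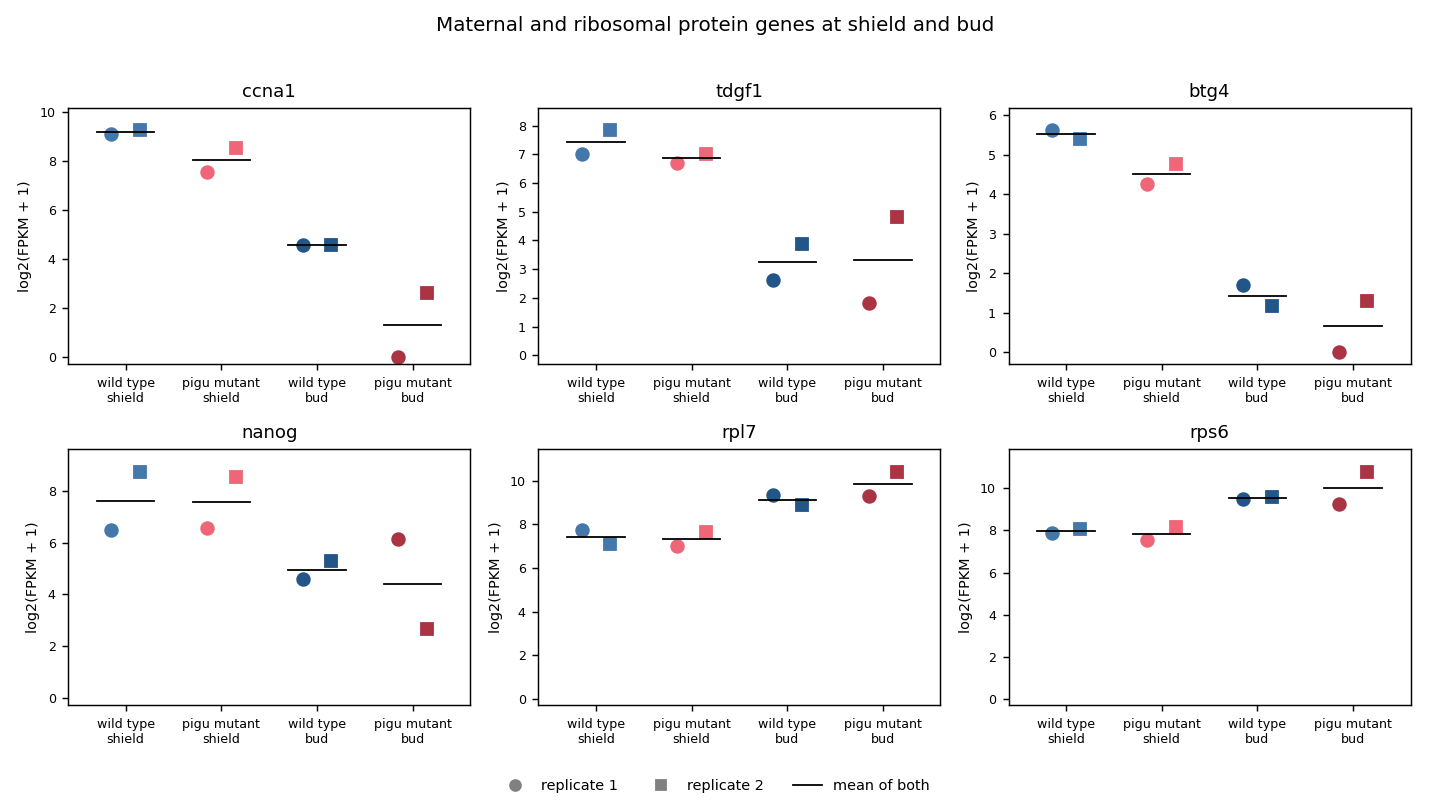
log2(FPKM + 1) of 4 maternal and 2 ribosomal protein genes in each library, with the mean of both as a line. ccna1 lies at 22.6 FPKM or less in the 4 bud libraries and at 188 or more in the 4 shield libraries, and rpl7 lies higher at bud in both genotypes.

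The interaction asks whether the genotype difference at bud departs from that at shield. Camera called 10 lists, and none of the 10 with an estimated correlation (smallest adjusted p = 0.68). Relative to all genes, the lists called higher were axial mesoderm (4.14, 11 of 11 members, camera adjusted p = 1.4e-08), Nodal targets (3, 13 of 14, 6.3e-08), mesendoderm (2.37, 15 of 18, 2.8e-05), the mitochondrially encoded genes (2.24, 13 of 13, 9.6e-14), neural ectoderm (2.13, 20 of 20, 1.4e-08), paraxial and lateral mesoderm (1.70, 0.00019), retinoic acid targets (1.40, 0.02), ribosomal protein genes (0.83, 2.7e-07) and adhesion genes (0.66, 0.046). After quantile normalization the mitochondrial value was 1.12 and the ribosomal value 0.03, where the latter call was lost, and the adhesion call was lost after median-of-ratios scaling. p53 genes had a difference of −1.09 (18 of 20 lower, 0.022), and this call was kept in 13 of 23 alternatives. It was lost with a pseudocount of 0.1, the filter at FPKM of 5, FPKM of at least 1 in all libraries, and without mutant shield replicate 1, wild type bud replicate 2 or either mutant bud library. The retinoic acid and adhesion calls were lost with the same pseudocount and the filter at FPKM of 5, adhesion with no filter, and adhesion and mesendoderm with FPKM of at least 1 in all libraries. Without mutant bud replicate 2 there were 4 calls, and without mutant bud replicate 1 or wild type bud replicate 1 there were 17. The axial mesoderm, mesendoderm, Nodal and mitochondrial calls were kept whichever single library was left out. Over the list alone, dkk1b passed among Nodal targets and among Wnt targets, and mt-atp8 among the mitochondrial genes (limma adjusted p = 0.025).

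limma called 0 genes for the interaction, with 199 at an unadjusted p under 0.05. Among genes that pass the filters of the rule, dkk1b had the smallest p on the higher side (log2 difference 7.36, SE 1.84, limma adjusted p = 1). It was followed by mt-atp8 (2.78, SE 0.75), six3b, fbxw11b and prdm14. On the lower side were GPHB5, the myosin light chain gene myl6, the sterol enzyme gene msmo1, dennd2da and plekho1a. Across the 13984 genes the genotype differences at shield and bud, which share no library, correlated at r = 0.13 (Spearman's rho 0.11), and those of stage in the 2 genotypes at r = 0.37 (rho 0.35). Genes are not independent replicates, so no p is given.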

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

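The tests that weigh the 3 patterns below were chosen only after the result was seen, while the list tests of the interaction and the count of sample splits were planned. The mitochondrial test first used the share of total FPKM and was replaced by the level of the 13 protein-coding genes, and the rule for the second somatic test was revised once its value had been seen.

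Singled out here are lists whose genotype difference at bud departed from that at shield by a test of the interaction. The median interaction on the log2 scale was 3.98 for axial mesoderm, 2.83 for Nodal targets, 2.21 for mesendoderm, 2.07 for the mitochondrially encoded genes, 1.97 for neural ectoderm, 1.54 for paraxial and lateral mesoderm, 1.24 for retinoic acid targets, 0.67 for ribosomal protein genes and 0.49 for adhesion genes. It was −1.25 for p53 and apoptosis genes. From these values the median of all genes, −0.16, was not taken off. None of the 10 held with an estimated correlation (smallest adjusted p = 0.68). The axial mesoderm, Nodal, mesendoderm and mitochondrial calls were kept whichever single library was left out. At shield, axial mesoderm, Nodal targets and mesendoderm lay at −1.03, −0.82 and −0.81 relative to all genes, and were not called. Their interaction thus also holds these low values at shield. In mutant bud replicate 1 the median difference from wild type bud was 0 for axial mesoderm and 0 for mesendoderm. Nodal targets had a mean log2 level there above both wild type bud libraries (1.88 and 1.75). Without mutant bud replicate 2 the median of all genes at bud was −0.95. Genes near 0 FPKM in wild type bud, such as noto, cannot fall with it. For these lists the kept calls therefore cannot show a rise at bud outside mutant bud replicate 2.

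The first pattern is the somatic marker lists that stood high in the mutant bud libraries. Somatic cells or their RNA in mutant bud replicate 2 may be the source. In that library 18 of 19 germ plasm genes lay below both wild type libraries, with a median log2 difference of −1.54. The middle 95% of lists matched on level lay between −0.66 and 0.65. That 5 of 7 somatic lists lay above both restates the pattern and does not bear on its source. The genes noto, pax2a, krt5 and ctslb had 109, 217, 239 and 264 FPKM in that library. Picking by hand under fluorescence is meant to leave out cells without GFP, but these values cannot show whether it did. Transcription of somatic genes by mutant PGCs stays open. In mutant bud replicate 1 the 74 members of the 5 lists called had a median difference of −0.22. This is the 99.7th percentile of lists matched on level, yet not above 0. The lists were chosen by a comparison that includes this library, so a high percentile is favoured by the choice and decides nothing. Germ plasm genes lay at percentile 95.9 in the same library.

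The second pattern is the low transamidase subunits. Fewer detected genes in the mutant libraries could account for it, since the median difference of the 5 subunits, −1.22 over both stages, is at the 8.25th percentile of matched lists. Loss of the transcripts in mutant cells cannot be told apart from it. Between the replicate 2 libraries, which detect similar numbers of genes, the median was −0.38, at percentile 38.6, where matched lists had −0.27. Mutant bud replicate 2 is among them and may hold somatic RNA, so this value does not speak for germ cells alone. pigk at 0.19 and 0.18 FPKM in the mutant replicate 2 libraries against 4.02 and 8.83 is 1 gene and decides nothing for the set.

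The third pattern is the mitochondrially encoded transcripts in mutant bud. Lower RNA yield or library complexity may raise them, as the library with fewer genes detected had the higher level in 4 of 4 groups. Against it as the whole account, mutant bud replicate 2 had a mean log2 level of 10.83 and detected more genes than wild type bud replicate 1, at 10.28. Somatic RNA in mutant bud replicate 2, which stays possible, could change both its level and its count of detected genes. This comparison therefore does not decide. A higher level in mutant cells at bud stays open too: replicate 2 of the mutant lay 1.58 above that of wild type, while 2 libraries of one group differed by up to 1.77. The share of total FPKM was 17.3% against 17.8%.

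In the comparison of genotype over both stages, the 8 libraries can be divided within stage in 18 ways, which is too few for a share under 0.05 (the smallest is 0.056). The real split called 0 genes and the highest other split 10, and with a real count of 0 a count of splits with as many calls carries no information. At an unadjusted p under 0.05 the real split had 597 genes and the highest other split 3676. The 6 splits that part replicate 1 from replicate 2 at shield had at least 1333, and the other splits apart from the real one at most 400. This points to a structure of the samples along the replicate numbers at shield, where libraries with few and many detected genes fall apart.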

How the results depend on the processing

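Leaving out both mutant shield replicate 1 and mutant bud replicate 2 and a filter at FPKM of at least 1 in all libraries were chosen after seeing the data. Of the somatic lists mutant shield replicate 1 was high only in the enveloping layer (mean log2 4.30), and it was the lowest shield library in the other 6. The causes of the changes below were not tested, except that an estimated correlation takes account of the shared variation of a list's genes. Of the 72 results for named genes, 1512 of 1544 alternatives gave the same side of the threshold, 32 a stronger result and 0 a reversed call, and 1533 kept the sign. As the named genes were not called, the same side of the threshold says little about their stability. The difference of pigu stayed below 0 in 22 of 22 alternatives at shield, in 21 of 22 at bud and in 22 of 22 over both stages; leaving out 1 library gave −2.97 to −0.24, −2.94 to 0.12 and −2.27 to −0.74. Lists were not run with robust moderation or the minimum fold change, and fitting only the libraries compared was not run over both stages or for the interaction. Where a group is left with 1 library it is assumed to vary like the others.

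For gene counts, all 0 as reported, leaving out 1 library gave 0 to 2 at shield, 0 in each case at bud, 0 to 3 over both stages, 0 to 1 for stage in wild type, 0 to 195 for stage in mutant (195 without mutant shield replicate 2) and 0 for the interaction. Over both stages 1 gene was called with the filter at FPKM of 5, the replicate block, robust moderation, array weights or adjusted p under 0.10. For stage in mutant the filter gave 3, median-of-ratios scaling 7, quantile normalization 7, the replicate block 5 and robust moderation 6. The replicate block gave 1 gene, mt-atp8, for the interaction, and moved no list count by over 1.5 times. It raised the genes with an unadjusted limma p under 0.05 from 201 to 395 at shield and from 677 to 1339 at bud. Over both stages they rose from 597 to 1199, where 699.2 would be found by chance. A count below chance in the main fit is therefore not evidence that the genotypes are alike. The labels do not say that the numbers pair samples; deviations of same-numbered libraries correlated at 0.33, 0.22 and 0.12 among wild type shield, mutant shield and wild type bud, and at 0.05, −0.01 and 0.02 with mutant bud. At bud, leaving out both mutant shield replicate 1 and mutant bud replicate 2 gave 237 genes, 10 higher and 227 lower.

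For lists, 3 called at shield, 12 at bud, 12 over both stages and 10 for the interaction, an estimated correlation or fry gave 0 in each. Leaving out 1 library gave 3 to 8 at shield (8 without wild type shield replicate 1, 7 without mutant shield replicate 2, 5 without mutant shield replicate 1 or either wild type bud library), 1 to 17 at bud, 2 to 17 over both stages and 4 to 17 for the interaction, the lowest of the last 3 without mutant bud replicate 2. At shield, median-of-ratios scaling gave 1 and adjusted p under 0.10 gave 5; for the interaction the latter gave 17. Without both mutant shield replicate 1 and mutant bud replicate 2 there were 5 at shield, 1 at bud and 2 over both stages. The filter on all libraries gave 3 at bud, 4 over both stages and 4 for the interaction. Depth is unknown, and differences of genes near FPKM of 1 are limited by the 5878 to 13007 genes detected per library.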

Other observations

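The test of a developmental lag was planned before the result was seen, and the test of the dissociation stress list by stage was chosen only after it.

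The heat shock gene hsp70.3 stood at 217 and 273 FPKM in mutant shield against 60.2 and 134 in wild type shield, and at 5.30 and 22.4 in mutant bud against 32.4 and 35.5 in wild type bud. It is a member of the dissociation stress list, in which 1 gene passed when adjusted over the list alone for stage in mutant (smallest adjusted p = 0.016), while the list was not called (camera adjusted p = 0.082). The reporter that labelled the cells carries the nanos1 3′ UTR, and the table cannot part its reads from those of nanos3, the present symbol of that gene. The values of nanos3 were 3014 and 9313 FPKM in wild type shield, 2885 and 20924 in mutant shield, 3792 and 7247 in wild type bud and 7285 and 1518 in mutant bud.

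A hypothesis set up in advance was that mutant germ cells lag behind wild type in their stage-dependent transcripts, which may make the genotype difference at bud run against the stage difference of wild type. With wild type libraries exchanged so that none was shared, Pearson's r across 13984 genes was 0 and −0.03 at bud (Spearman's rho 0.01 and −0.03) and −0.07 and −0.19 at shield (rho −0.09 and −0.19). The values near 0 at bud leave the question open, since genes are not independent replicates and the difference in detected genes between libraries enters both quantities.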
